A study of Equus caballus with 56 samples.

How the data were processed

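Genomic DNA of 54 horses, isolated from blood or hair follicles per the labels' protocols, was hybridised to 2-colour oligonucleotide arrays against DNA of a Thoroughbred reference horse, and each of the 2 reference horses was also hybridised against itself. Per the labels, the test horse carried Cy5 and the reference Cy3 on every array, males were set against one reference horse and females against the other. The design text of the series is less clear: it names the first reference for male and female affected horses and the second for female ones, so the label of each array was followed. X medians of the 6 female affected horses outside the slide of low signal lay between -0.04 and 0.04, where a male reference would raise X. By these labels sex and reference horse are the same term in every fit below. Whether animals shared a sire, a dam or a stable is not given in the sources used here.

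For 56 arrays the deposited series table gives a log10 ratio per spot, and scanner output with spot intensities was used for the 18 arrays of affected and control horses. Per the file headers, the scanner intensities are processed signals from Agilent Feature Extraction versions 10.10.1.1 (4 arrays) and 11.0.1.1 (14 arrays), which are background-subtracted and dye-normalised by a linear factor. The submitters' processing notes name Agilent Feature Extraction 11.0.1.1 for the series. On the 18 arrays with scanner output the deposited log10 ratio equalled the scanner's log ratio of red over green to within 5e-11, which settles its scale and that it is red over green for those arrays. For the breed panel the same was taken from the labels. Which horse carried which dye rests on the labels for all arrays. Median log2 ratios of the deposited columns ran from -0.11 to 0.09 before centring.

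Log10 values were converted to log2, an exact 0 was treated as missing, control spots were left out, repeated spots of 1 probe were averaged, and each array was centred on its autosomal median, with no loess or quantile step. This left 412441 probe positions of 60 bases, 388901 of them on 31 autosomes with a median spacing of 5531 bases. The scanner's outlier spots were left out of the scanner values only. They stayed in the series table values used for calls, for comparisons with the panel and for all corrected fits described below. On summer RAO affected 2 they made up 43.0% of spots. Positions come from the probe names. The genome build is not given in the sources used here, so coordinates below are those of the array design, and no gene was named: gene lists and 2 loci fixed for testing beforehand are not analysed here. Probes that the names place on a chromosome 32, outside the 31 autosomes, were kept out of the autosomal and X results. All 2793 have names starting with E, of which X has 0, and their last position, 124104394, is near that of X, 124110487. Their medians were -0.29 and -0.27 on RAO affected 3 and 4, where X lay at -0.56 and -0.53. They may thus be probes of X, which the X results would then lack, but this was not settled.

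Copy number calls came from a search for intervals with the largest score. The score was the absolute sum of log2 values, each divided by the robust standard deviation of the array, over the square root of the number of probes. Values were limited to 5 standard deviations. A call needed a score of at least 6, at least 5 probes and an absolute mean log2 of at least 0.3, and held at most 1000 probes. Calls of all 54 horses that overlapped by at least 1 base were merged into regions, and the mean log2 ratio of each region and array entered the tests. Tests were limma with Benjamini-Hochberg adjustment and a threshold of 0.05 for regions and probes, Fisher's exact test for carriers, and a two-sided permutation test with 100000 resamples within sex for calls per horse. Sex was a covariate unless it was the comparison. RAO against summer RAO, and summer RAO against its controls, used the scanner values. Their corrected fits, described below, used the series table values instead.

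These designs, the thresholds, the alternatives named as planned and the rule for named regions were fixed before the data were examined. Named are the regions that passed in each comparison, at most the 10 with the smallest p. Where none passed, the 5 with the smallest unadjusted p are named as not passing. The 15 regions called in most horses, the regions called in at least 2 affected horses and in no other horse, at most 10, and the 5 longest regions complete the rule. Large groups are summarised below with examples.

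After the calls had been seen, a correction was added. The first 2 probe patterns shared between arrays, which held 39.4% and 16.2% of the variance of the scaled arrays, were estimated by a singular value decomposition and removed from each array. Removal of 2, 5 and 8 patterns was tried, and 2 was kept because the female reference against itself then still gave 0 calls. The male reference against itself gave 25 corrected calls, as many as before correction, against a median of 79 in panel horses. Results with this correction are alternatives chosen after seeing the data and are named as corrected throughout.

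On simulated arrays with a robust standard deviation of 0.276, the search found 100% of intervals of 10 probes at an absolute log2 of 1 and 55% at 0.5, and made 0 calls elsewhere. Intervals of 6 probes at 0.5 were found in 5% of cases, and at a robust standard deviation of 0.431 the search found 30% of 6 probes at 1, 2.5% of 10 probes at 0.5 and 30% of 20 probes at 0.5, so small changes on the noisier arrays are mostly missed. In simulated arrays with 2 added patterns it found 37 of 40 intervals with 20012 other calls, and after pattern removal 40 of 40 with 0 other calls. As many patterns were removed as had been added, and each interval lay on a single array. Whether removal takes away changes shared by several arrays was therefore not tried. For the corrected comparison of affected horses with the panel, limma found 87 of 100 simulated differences of 0.2 and 99 of 100 of 0.4 in sets of 1000 regions, with 6 unchanged regions called.

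The number of arrays limits the precision of every value. Robust standard deviations of the arrays ran from 0.10 to 0.73 on the log2 scale. Summer RAO control 1 and summer RAO affected 2 shared a slide on which 2.96% and 10.6% of spots were well above background in both channels, against 96.7% to 99.8% on the other 16 arrays with scanner output. Both stayed in the tests and were also left out as an added alternative, as were RAO affected 3 and 4, whose X and Y probes go against their labelled pair of sex and reference.

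Per the labels all arrays share 1 dye orientation. Of 1540 pairs of arrays 102 correlated below -0.3 over all probes, 52 of them among the 765 pairs with the same reference horse, with a lowest r of -0.65 and a highest of 0.94. Because the dyes are stated and different horses can carry opposite changes against a reference, the stated direction was kept. After correction 36 pairs lay below -0.3, 7 of them with the same reference. No 2 arrays held identical values. A check of signs over regions where nearly all arrays of a reference share a sign is described among the other observations, and it did not settle the direction of every array.

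Alternatives changed the probe minimum, the log2 and score thresholds, the merging of calls, removal of a running median of 501 probes (the genomic wave), covariates, groups, scaling, background correction (normexp with an offset of 50), dim probes, slide as a random block and left-out replicates. Slides of the panel arrays are not given in the sources used here, so array batch and disease label cannot be told apart in the comparison of affected horses with the panel. Breed goes with these groups too: Swiss Warmbloods are 8 of the 16 affected and 3 of the 36 panel horses. No breed term was fitted in that comparison. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and data.table (version 1.17.8).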

Results

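Copy number was measured by array comparative genomic hybridisation in 12 horses labelled as affected by recurrent airway obstruction (RAO, a chronic asthma-like disease of the lower airways), 4 affected by a form labelled summer RAO, 2 summer RAO controls and a panel of 36 horses of 16 breeds. The panel held 20 males and 16 females, among them 2 Przewalski's Horses, and its disease state is not given in the sources used here. On each array a horse's DNA was set against that of a Thoroughbred of the labelled sex. A positive log2 ratio stands for more signal from the horse than from the reference and a negative one for less. These are read below as more and fewer copies. Whether a ratio came from copy number or from another difference in DNA or probes was not tested. The 2 reference horses hybridised against themselves gave the background: 25 autosomal calls in the male and 0 in the female. On X and Y probes, where horse and reference of 1 sex should be equal, 50 arrays had medians between -0.18 and 0.05 on X and between -0.46 and 0.36 on Y, and RAO affected 3 and 4 stood apart at -0.56 and -0.53 on X and 1.34 and 1.63 on Y. The 56 arrays limit the precision of all values, and p-values measure the spread between these animals.

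**Figure D1:**
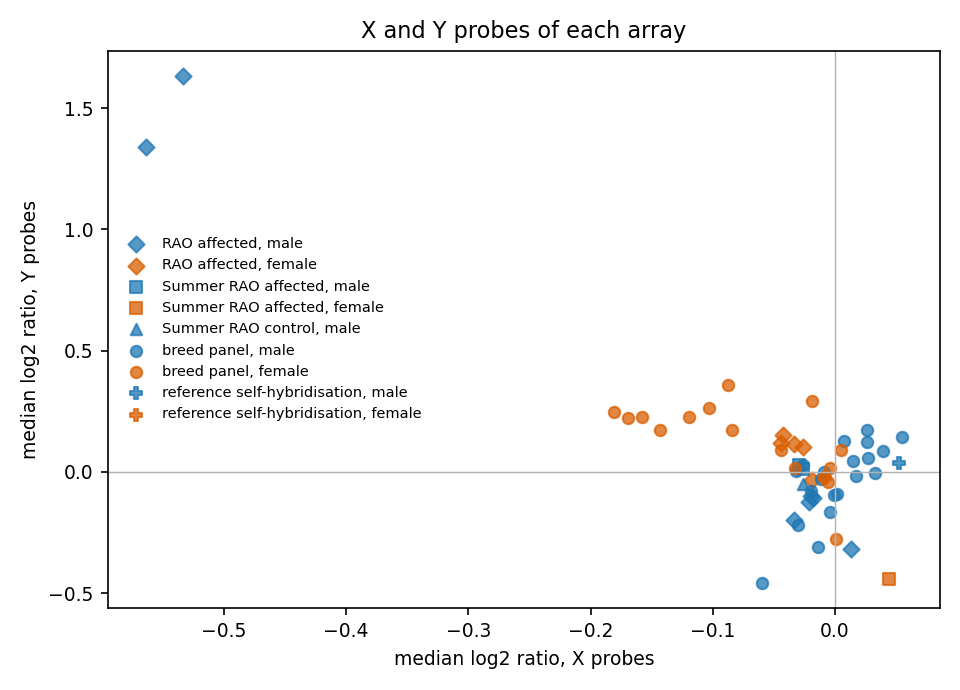
Median log2 ratio of X probes (horizontal axis) and Y probes (vertical axis) per array, without the 2 arrays of the slide with low signal; the marker gives the group and the colour the labelled sex. RAO affected 3 and 4, labelled male, lie at the upper left, apart from all other arrays.

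The first question was where in the genome copy number varied. Merged regions of chromosomes 1, 20, 12 and 7 held a call in nearly every horse: chromosome 1 from 149789251 to 160727716 in 52 of 54 horses, chromosome 20 from 23928600 to 28671372 in 51, chromosome 12 from 12070725 to 16900366 in 50 and chromosome 7 from 72140369 to 75160136 in 50. A merged region chains overlapping calls, and a horse counted with any call inside it, so these are not single changes shared by the horses. Over the whole chromosome 1 region the mean log2 ratio was -0.11 in affected and -0.12 in panel horses. The other 11 of the 15 regions called in most horses were called in 41 to 49. On chromosome 12 the mean log2 ratio of the arrays ran from -1.10 to 0.36, with losses in 40 horses and gains in 29. In all, 18501 calls (1958 gains and 16543 losses) merged into 1081 autosomal regions with a median length of 192.1 kb, of which 739 were called in at least 2 horses. Gains and losses follow the stated direction of each array, which a check of signs left unsettled for 6 arrays: RAO affected 3, 4, 7 and 10 and 2 panel horses. All other female arrays had 0 regions to check at the limits fixed beforehand, so their direction was not tested there. With the 6 arrays turned, the same calls made 3954 gains and 14547 losses. Of these arrays, RAO affected 7 correlated at 0.93 with RAO affected 5, 6 and 8, which were not turned. The longest region lay on chromosome 17 from 29487459 to 67282073, 37.8 Mb, and held calls in 39 horses. It has 5170 positions and a call held at most 1000 probes, so no single call spanned it.

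These regions covered 58.7% of autosomal positions, and the regions from corrected values covered far less. After removal of 2 probe patterns shared between arrays, a step chosen after the calls had been seen, 4207 calls (1917 gains and 2290 losses) merged into 1114 regions with a median length of 40.9 kb that covered 6.71% of positions. Of these, 989 overlapped a region of the first set, while 465 of the 1081 first regions overlapped a corrected one. The same 4 chromosomes led: chromosome 12 from 12265172 to 15740105 was called in 51 horses, chromosome 1 from 158802567 to 160744336 in 48 and from 155316862 to 156856221 in 46, chromosome 7 from 73039711 to 73725941 in 44 and chromosome 20 from 31949776 to 33135971 in 43. On chromosome 12 the corrected mean log2 ratio ran from -1.42 to 0.79 between arrays, with gains in 45 horses and losses in 33. Within chromosome 20, the region from 28328316 to 28601739 was called in 40 horses and reached -1.70. On chromosome 29 from 28593238 to 28871904, called in 35 horses, array means ran from -1.81 to 0.63. The 5 longest corrected regions, 4.14 to 7.02 Mb, all lay on chromosome 16. There the male Przewalski's Horse averaged 0.41 from 53289211 to the last position, 87364803. This compares with -0.06 to 0.02 in 53 other arrays (those of the low-signal slide left out), the female Przewalski's Horse at -0.01 among them.

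**Figure D2:**
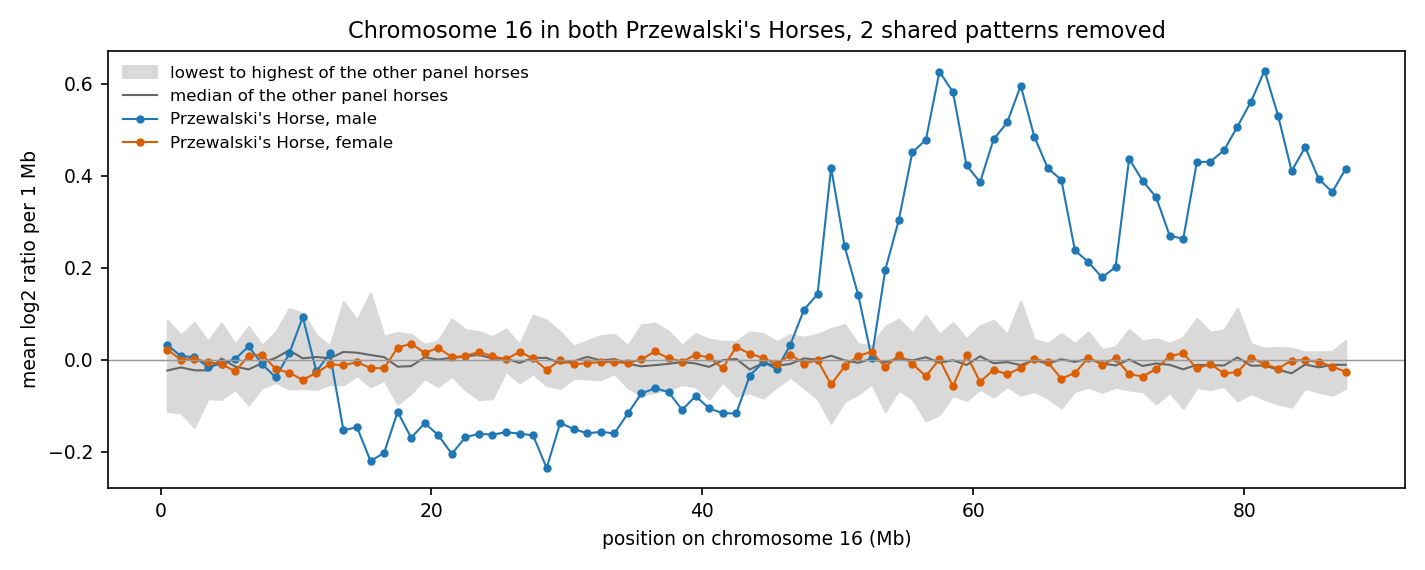
Mean log2 ratio per 1 Mb along chromosome 16, after removal of 2 shared patterns, in both Przewalski's Horses; the line and band give the median and the range of the other panel horses. The male lies above the band from 47 to 52 Mb and from 53 Mb to the end, and below it over most of 13 to 43 Mb, and the female stays near 0.

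Affected horses were compared with the panel first by their number of calls. With centred values, affected horses had 413 ± 401.9 autosomal calls (SD, n = 16) and panel horses 308.9 ± 271.1 (SD, n = 36), a difference of 104.1 that did not exceed the spread between horses (two-sided permutation test within sex, p = 0.281). Gains were fewer in affected horses, 15 ± 10.3 against 47.2 ± 51.4 (permutation p = 0.0132), and losses numbered 398 ± 404.2 against 261.6 ± 270.7 (p = 0.160). With the 6 arrays of unsettled direction turned, gains were more in affected horses, 130.9 ± 262 against 51.2 ± 58 (p = 0.0575), and losses numbered 282.1 and 257.7 (p = 0.798). With these left out, gains were again fewer, 12.8 against 45.2 (p = 0.0187). The difference thus held without those arrays, and its direction changed with them turned. RAO affected 7, with 689 losses, was among those turned, although it correlated at 0.93 with RAO affected 5, 6 and 8, which were not. After correction the counts were 71.7 ± 23.3 and 82 ± 31.5 (p = 0.257), with 36.1 gains in affected horses and 35.5 in the panel (p = 0.916), so the lower number of gains did not hold.

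**Figure D3:**
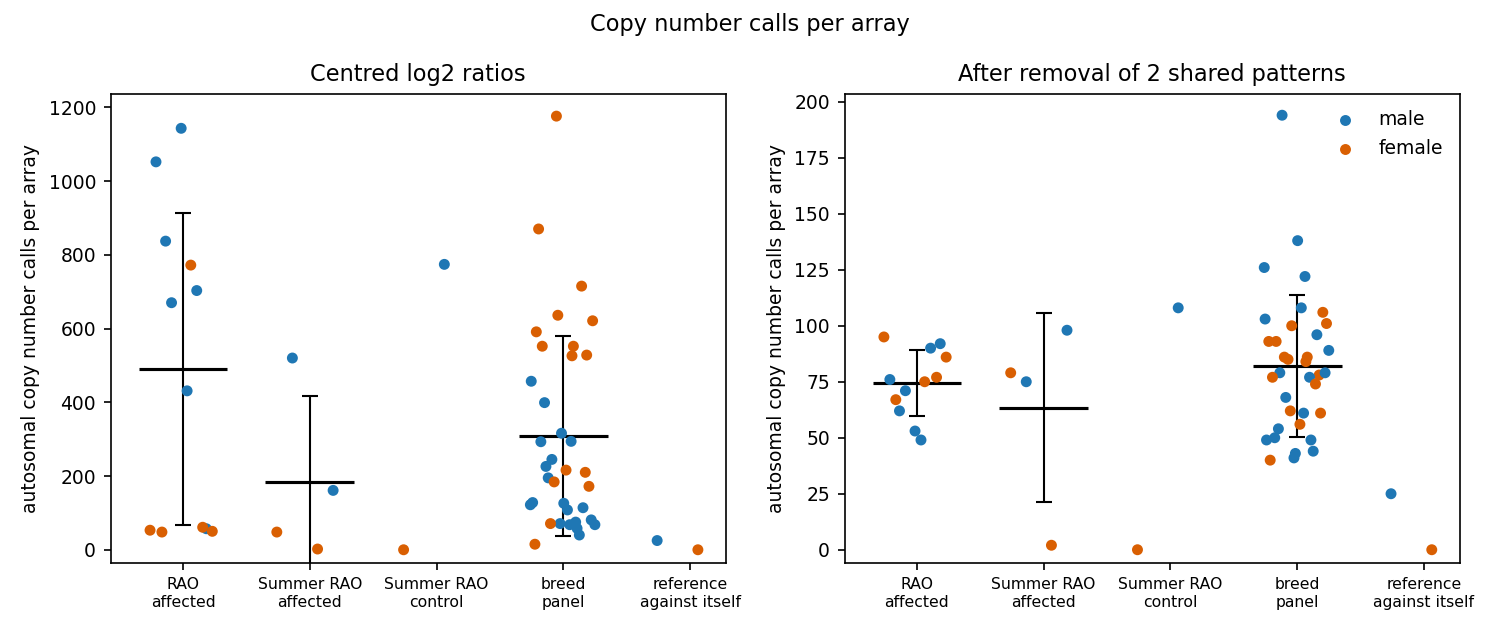
Autosomal copy number calls per array by group, with centred values on the left and after removal of 2 shared patterns on the right; points are arrays coloured by the horse's sex, horizontal lines are group means and bars are SD for groups of more than 2. Counts run from 0 to 1176 on the left and from 0 to 194 on the right, and affected horses and panel overlap in both.

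Some regions were called only in affected horses. Losses on chromosome 19 from 38823244 to 38957800 were called in 5 affected horses and in no other, and losses on chromosome 15 from 53368545 to 53400574 and on chromosome 8 from 33820903 to 34147848 in 4 each. On chromosome 19 the mean log2 ratio was -0.20 ± 0.22 in affected horses and -0.15 ± 0.22 in the panel (SD, n = 16 and 36), so the groups overlapped. The region with the smallest p, on chromosome 7 from 85423512 to 85639811, was called in 6 affected horses and 0 panel horses. A summer RAO control had a call there too, so it is not a region of affected horses only. Fisher's exact test of carriers gave 0 of 1081 regions past the threshold after adjustment (adjusted p = 0.425 for that region), with 55 at an unadjusted p under 0.05. After correction, 17 regions were called in at least 2 affected horses and in no other horse. The 10 of them that the rule names were called in 2 affected horses each, for example gains on chromosome 3 from 115886731 to 115966060 and on chromosome 18 from 13648701 to 13818762. Corrected carriers gave 0 of 1114 past the threshold, with 9 at an unadjusted p under 0.05. The smallest p there belonged to chromosome 29 from 21510728 to 21600157, called in 11 affected and 5 panel horses (adjusted p = 0.189).

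In the values themselves, the means of affected horses and panel differed in 2 regions after correction, with ranges that overlapped in both. Breeds also differed between these groups, and breed was not in the fit. Chromosome 7 from 61440247 to 61476457 averaged -0.15 ± 0.20 in affected and 0.05 ± 0.10 in panel horses (SD, n = 16 and 36), a difference of -0.20 ± 0.04 (SE, limma, adjusted p = 0.0136), and in the stated directions all 16 affected horses lay below the panel mean. Chromosome 5 from 58964324 to 58974636 averaged 0.13 ± 0.16 and -0.05 ± 0.12, a difference of 0.18 ± 0.04 (SE, adjusted p = 0.0144), and all 16 lay above the panel mean. Both calls ended with the 6 unsettled arrays turned, and that of chromosome 5 also ended with these left out. Among the 6, RAO affected 7 was turned against RAO affected 5, 6 and 8, with which it correlated at 0.93. The 6 arrays were picked for signs against those of panel arrays, so turning them can by itself shrink such differences. With these turned, 0 regions passed in limma (126 at an unadjusted p under 0.05), and the 2 differences were -0.09 ± 0.05 and 0.10 ± 0.04 (SE, adjusted p = 0.432 and 0.414), with 13 of 16 affected horses below and 14 above the panel mean. With these left out, all 12 affected horses stayed on the same sides. Chromosome 7 then passed (-0.18 ± 0.04, SE, adjusted p = 0.0286) and chromosome 5 did not (0.16 ± 0.04, SE, adjusted p = 0.122). The chromosome 7 difference was -0.14 in males alone (adjusted p = 0.128) and -0.26 in females alone (adjusted p = 0.0144), and that of chromosome 5 was 0.18 in males (adjusted p = 0.0613) and 0.17 in females (adjusted p = 0.0853). With the low-signal array and RAO affected 3 and 4 left out, 10 corrected regions passed, 5 higher and 5 lower.

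With centred values limma found 0 of 1081 regions past the threshold, with 16 at an unadjusted p under 0.05. The 5 with the smallest p, none of which passed, were chromosome 17 from 68264490 to 68289403 (difference 0.18 ± 0.05, SE, adjusted p = 0.584), chromosome 10 from 23835646 to 24042106 (0.11 ± 0.03), chromosome 1 from 172011462 to 172057658 (0.13 ± 0.05), chromosome 20 from 4977740 to 5004117 (0.13 ± 0.05) and chromosome 11 from 21360102 to 21371730 (-0.11 ± 0.04). With the stated directions the 0 hides opposite differences in the sexes. In 9 affected against 20 panel males 646 regions were lower and 6 higher, and in 7 affected against 16 panel females 658 were higher and 15 lower. An interaction of group and sex passed in 805 regions with centred and in 94 of 1114 with corrected values. Of the affected males 4 are of unsettled direction. With the 6 arrays turned, 0 regions passed in males (limma, 31 at an unadjusted p under 0.05) and 674 in females, and the interaction passed in 41 centred and 25 corrected regions. With these left out, 624 were lower and 6 higher in males, 748 higher and 19 lower in females, and the interaction passed in 804 centred regions and 0 corrected ones (221 at an unadjusted p under 0.05).

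**Figure D4:**
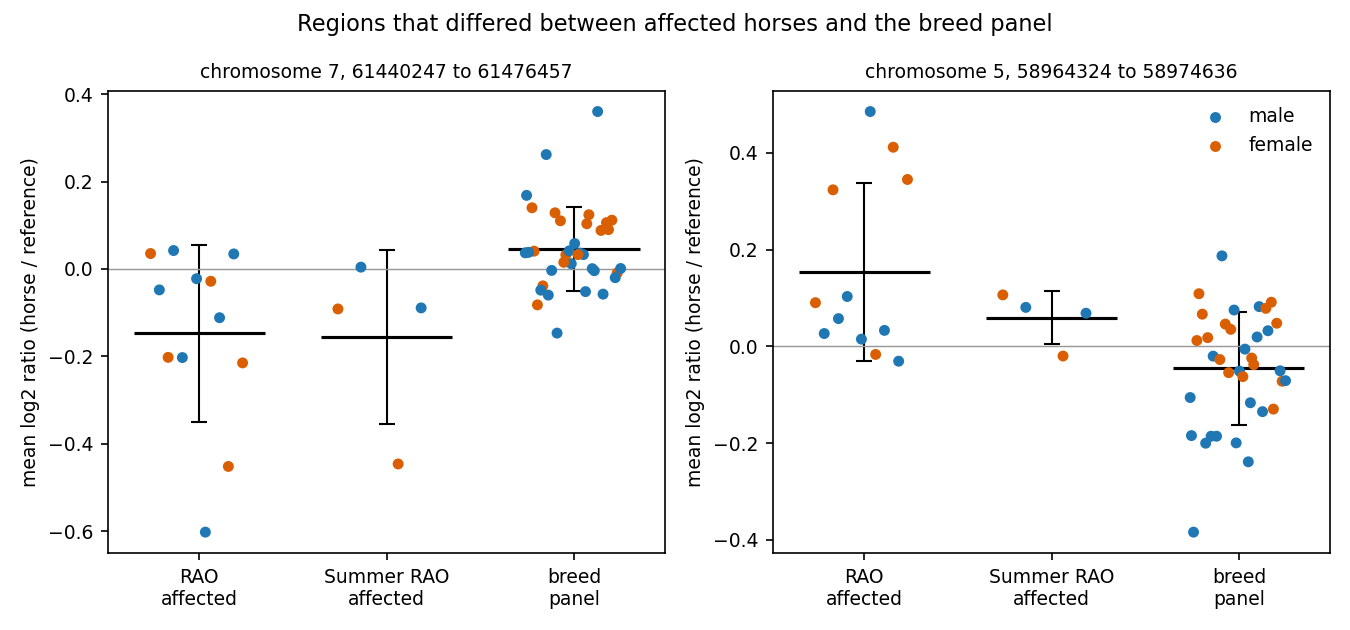
Mean log2 ratio per array, after removal of 2 shared patterns, of the 2 regions that passed the test of affected horses against the panel; points are horses coloured by sex, lines are group means and bars SD. With the stated direction of each array, all 16 affected horses lie below the panel mean on chromosome 7 and above it on chromosome 5, and the groups overlap in both.

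Single probes also differed. Of 412404 tested positions, 209 passed (11 higher and 198 lower in affected horses, limma), with a median absolute difference of 0.41. With the 6 arrays of unsettled direction turned 13 passed, all lower, and with these left out 164 (5 higher and 159 lower). The 209 were scattered: 205 had no other such position within 5 positions. Of the 190 on autosomes 17 (8.95%) lay in a corrected region, where 6.71% of autosomal positions lie, and the other 19 were on X or unplaced. The smallest p belonged to a probe on chromosome 6 from 8979317 to 8979376, at -0.32 ± 0.22 in affected and 0.11 ± 0.17 in panel horses (SD, adjusted p = 0.000412). A probe on chromosome 10 from 29772002 to 29772061 was higher in affected horses, at -0.23 ± 0.39 against -0.83 ± 0.33 (adjusted p = 0.000947). After correction 1195 positions passed, 270 higher and 925 lower, and 1143 of them had no other within 5 positions; 2 passed with the 6 arrays turned and 461 with these left out.

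Holding breed fixed, 8 affected and 3 panel Swiss Warmbloods differed in no region past the threshold: limma gave 0 of 1081, with 10 at an unadjusted p under 0.05. The smallest p was on chromosome 4 from 92493321 to 92513950, at -0.12 ± 0.10 in affected and 0.05 ± 0.12 in panel horses (SD, difference -0.23 ± 0.07, SE, adjusted p = 0.999). The other 4 of the 5 smallest, which did not pass either, lay on chromosome 9 from 13206929 to 13210684 (0.28 ± 0.09), chromosome 18 from 82409756 to 82433989 (0.26 ± 0.10), chromosome 20 from 4977740 to 5004117 (0.22 ± 0.08) and chromosome 5 from 99124362 to 99138358 (0.14 ± 0.06). After correction 0 of 1114 passed, with 99 at an unadjusted p under 0.05, the smallest p being that of chromosome 19 from 37922176 to 37945854 at -0.07 ± 0.07 against 0.23 ± 0.14 (adjusted p = 0.168). Without the only panel male of the breed, the differences on chromosomes 9, 18, 20 and 5 fell to 0.10, 0.11, 0.05 and 0.06. With only the 4 affected arrays of the later extraction protocol, all male, 264 regions passed, 249 of them lower. With sex in the fit this sets them against that 1 panel male, assumed to vary like the others.

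RAO and summer RAO horses were set against each other to compare the 2 disease labels. After correction 37 regions passed, 14 higher and 23 lower in RAO, and 4 with the RAO arrays of unsettled direction turned. With slide as a random block (slide correlation 0.529) 2 passed, those of chromosomes 2 and 6 below. Chromosome 5 from 31851817 to 31880602 averaged -0.06 ± 0.17 in 12 RAO and 0.52 ± 0.32 in 4 summer RAO horses (SD, difference -0.56 ± 0.10, SE, adjusted p = 0.00824), chromosome 2 from 86017148 to 86043416 averaged -0.04 ± 0.07 and 0.19 ± 0.04 (adjusted p = 0.000845), and chromosome 14 from 18329831 to 18355308 averaged -0.04 ± 0.16 and 0.34 ± 0.05 (adjusted p = 0.00891). Chromosome 6 from 71776259 to 71786128 was higher in RAO, at 0.06 ± 0.10 against -0.36 ± 0.02 in the 3 summer RAO horses with a value (adjusted p = 0.00225), as was chromosome 7 from 53533401 to 53621723, at 0.03 ± 0.06 against -0.18 ± 0.09 (adjusted p = 0.00594). In all 5 of these regions every RAO horse lay on 1 side of the summer RAO mean. With the slide block the differences of chromosomes 5, 14 and 7 were -0.58, -0.35 and 0.19 with adjusted p of 0.0572, 0.0619 and 0.0612, so their calls ended there. All 5 passed with the RAO arrays of unsettled direction left out, and of the 5 only chromosome 6 passed with these turned (0.37, adjusted p = 0.0395).

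The corrected fit used the series table values, with which 3 of 1081 regions passed in limma before correction. With the scanner values as such, 0 of 1081 regions passed in limma, with 366 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0530. The 5 with the smallest p, none past the threshold, were chromosome 5 from 18030125 to 18211591 (-0.30 ± 0.06, SE), chromosome 24 from 38191868 to 38556652 (0.13 ± 0.03), chromosome 7 from 96323463 to 96497957 (0.21 ± 0.04), chromosome 30 from 6177626 to 6253036 (0.21 ± 0.05) and chromosome 2 from 15095215 to 15329851 (-0.17 ± 0.04). With slide as a random block (correlation 0.677) 0 passed and 97 had an unadjusted p under 0.05, while 616 passed with only the arrays of the later extraction protocol and 496 without the RAO arrays of unsettled direction. With these arrays turned 0 passed, 34 had an unadjusted p under 0.05, and the median difference went from -0.071 to 0.037. No slide held horses of both labels, so no value within a slide can be had.

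Summer RAO affected horses were set against the 2 labelled controls. In the 4 affected and 2 controls, the region of chromosome 6 from 34420528 to 34428651 averaged -0.40 ± 0.07 and -0.08 ± 0.09 (SD) and that of chromosome 7 from 75174395 to 75188317 averaged 0.18 ± 0.07 and -0.04 ± 0.03, neither past the threshold (limma, adjusted p = 0.760 for both). The other 3 of the 5 smallest p, not past the threshold either, lay on chromosome 8 from 44418335 to 44449547, with a value in 3 affected horses and 1 control, on chromosome 8 from 19930104 to 19934939 and on chromosome 12 from 24117101 to 24141483. Limma gave 0 of 1081 past the threshold and 58 at an unadjusted p under 0.05, 0 and 52 after correction, and 0 and 34 with slide as a random block, whose slide correlation of -0.716 is not that of a shared slide effect. With slide as a fixed block and no sex term, 0 passed, with 203 at an unadjusted p under 0.05. Within the slide of summer RAO affected 1 (female) and control 2 (male), affected minus control was -0.31 on chromosome 6 and 0.14 on chromosome 7. Within the low-signal slide, with 1 female of each, it was -0.35 and 0.17. On chromosome 12 from 24117101 the slides disagreed, 0.11 and -0.27, and the 2 regions of chromosome 8 had both values on the first slide only (0.79 and 0.72). Without the slide of low signal, which leaves 3 affected horses and 1 control, 10 regions passed.

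The panel males and females were compared to find where the 2 reference horses, or the sexes, differ. After correction, chromosome 10 from 595307 to 1463056 averaged -0.22 ± 0.08 in 20 males and 0.08 ± 0.11 in 16 females (SD, difference -0.30 ± 0.03, SE, limma, adjusted p = 8.7e-08), and chromosome 9 from 1932378 to 1947566 averaged -0.25 ± 0.18 and 0.17 ± 0.12 (adjusted p = 4.1e-07). Chromosome 24 from 19321525 to 19323539 was higher in males, at 0.76 ± 0.44 against -0.33 ± 0.51 (adjusted p = 1.2e-06), as was chromosome 4 from 51359063 to 51399625, at 0.35 ± 0.24 against -0.19 ± 0.23 (adjusted p = 2.9e-06). In all, 251 of 1114 corrected regions differed, 156 higher and 95 lower in males. With the 2 panel arrays of unsettled direction turned, 178 were higher and 185 lower, and with these left out 188 and 160. Males and females had different reference horses, so these differences belong to sex and reference together.

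With centred values 660 of 1081 regions differed, 632 higher and 28 lower in males. With the panel arrays of unsettled direction turned, 734 were higher and 130 lower, and with these left out 745 and 153. Most differences were thus higher in males in each case, but the number of lower regions depended on those arrays. With breed as a fixed block, a fit added after the data had been seen, 127 differed. Without this block the median difference over regions was 0.12 against 0.0031 after correction. The smallest p were on chromosome 29 from 21510728 to 21600157, at 0.08 ± 0.08 in males and 0.45 ± 0.17 in females, chromosome 24 from 19311010 to 19325019, at 0.32 ± 0.19 and -0.13 ± 0.19, and chromosome 20 from 23044336 to 23072852, at 0.32 ± 0.26 and -0.21 ± 0.18. Chromosome 16 from 26283503 to 26314643 had the largest difference among the 10 with the smallest p, 0.60 ± 0.49 against -0.03 ± 0.21. On X, 77 of 185 regions differed (60 higher, 17 lower; 32 with the breed block), led by 111311420 to 111361633 at 0.11 ± 0.13 and 0.53 ± 0.20 (adjusted p = 6.3e-07). With the panel arrays of unsettled direction turned, 75 X regions were higher and 35 lower, and with these left out 78 and 39. With all horses and affected status as a covariate, 11 autosomal regions (5 higher, 6 lower) and 1 X region passed.

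Przewalski's Horse, the only taxon of the panel that is not a domestic breed, differed from the domestic breeds in 40 corrected regions and 1 centred region. After correction, chromosome 20 from 28328316 to 28601739 was at -1.70 and -1.56 in its 2 horses and at -0.01 ± 0.20 (SD) in 34 horses of domestic breeds, a difference of -1.63 ± 0.14 (SE, limma, adjusted p = 3.5e-11). Chromosome 27 from 33417613 to 33429732 was at 0.88 and 0.97 in the Przewalski's Horses and -0.03 ± 0.16 in the others (adjusted p = 1.8e-07), and chromosome 5 from 47250326 to 47347088 at 0.50 and 0.45 against -0.03 ± 0.03 (adjusted p = 1.2e-11). Chromosome 10 from 62946292 to 63091967 (0.69 and 0.30), chromosome 20 from 50429388 to 50538233 (0.69 and 0.32) and chromosome 30 from 30030684 to 30059291 (0.45 and 0.44) were higher as well. All 6 of these regions lay outside the range of the 34 others in both horses and passed with either horse alone.

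Of the 40 corrected regions 22 were higher and 18 lower, and 9 passed without the male and 47 without the female. Of the other 4 among the 10 with the smallest p, chromosome 1 from 181262601 to 181290272, chromosome 2 from 111450596 to 111495060 and chromosome 11 from 46924886 to 46927971 were lower, chromosome 1 from 27894974 to 27913721 was higher, and each lost its call without 1 or the other horse. With centred values 1 region passed, chromosome 1 from 27893479 to 27913721, at 0.47 ± 0.11 against 0.02 ± 0.13 (SD, difference 0.45 ± 0.09, SE, adjusted p = 0.0270). It did not pass with either horse alone (adjusted p = 0.132 and 0.385), and the median difference over regions moved from -0.11 to 0.05 with the correction.

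**Figure D5:**
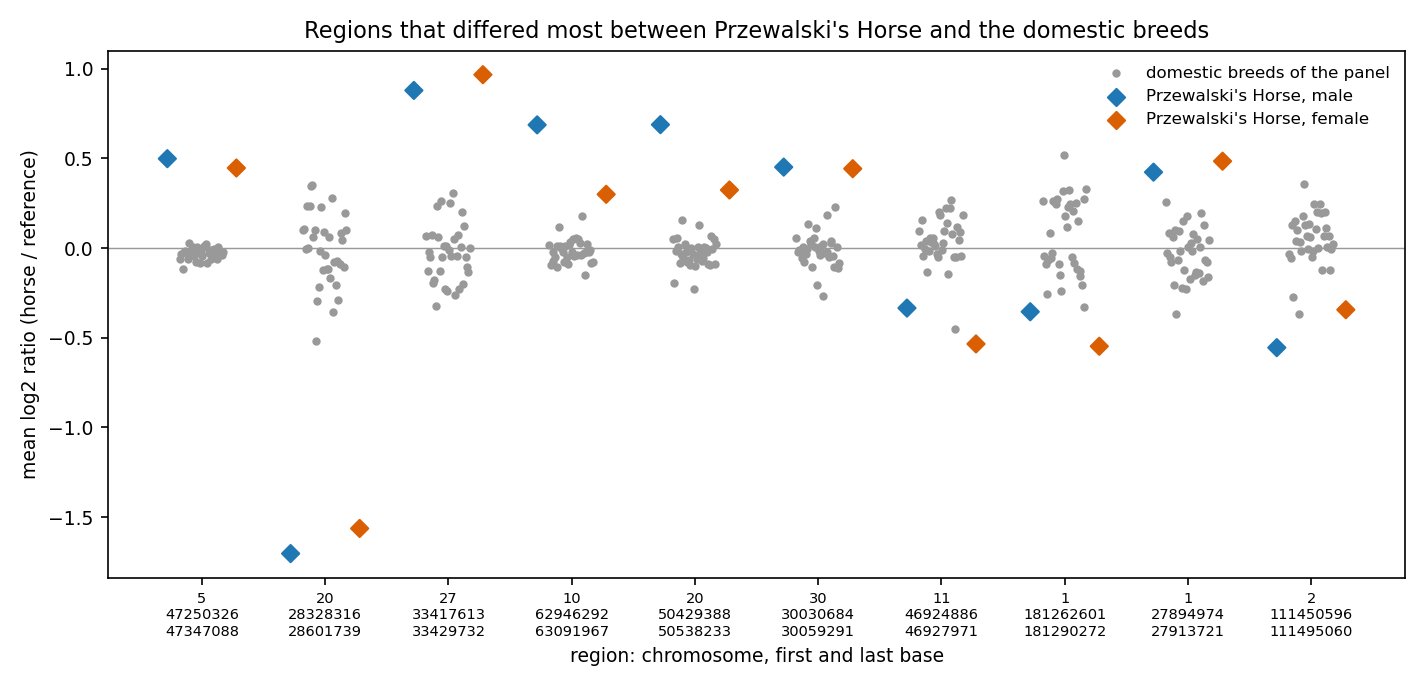
Mean log2 ratio, after removal of 2 shared patterns, of the 10 regions with the smallest p between Przewalski's Horse and the domestic breeds of the panel; diamonds are the 2 Przewalski's Horses and grey points the 34 other panel horses. Both Przewalski's Horses lie near -1.6 on chromosome 20 from 28328316 and above all others on chromosome 5 from 47250326.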

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

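The tests of a female test horse, of exchanged dyes and of shared probe patterns behind the opposite sexes, the splits that keep slides whole and the fits with arrays turned or left out were chosen after the results had been seen, as were all corrected values. The reference score was fixed before it was computed.

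A signal outside the compared measurements lay on the X and Y probes of RAO affected 3 and 4, both labelled male on the male reference. Their X medians were -0.56 and -0.53 and their Y medians 1.34 and 1.63, while 50 other arrays stayed between -0.18 and 0.05 on X and between -0.46 and 0.36 on Y. A female test horse would raise X and an exchange of dyes leaves a same-sex pair at 0, and both X medians, -0.53 and -0.56, argue against each of these alone. Both together would lower X and raise Y, so the medians do not argue against that, and it was not tested. A candidate explanation is the female reference horse on both arrays: over 251 autosomal regions that separate panel males (score 1) from panel females (score 0), the 2 arrays scored 0.17 and 0.33, nearer the females. It stays open, because 8 other affected and control males scored from -0.07 to 0.92, so the score does not tell the references apart outside the panel; no biological explanation was tested.

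The difference between affected horses and panel differed between the sexes in 805 regions with centred values and in 94 with corrected values, by a test of the interaction. Males were lower in 646 regions and females higher in 658, and these opposite shifts cancel in the joint comparison. With the 6 arrays of unsettled direction turned, the counts were 41 centred and 25 corrected, and with these left out 804 and 0. The centred count thus holds without these arrays but not with these turned. Whether the corrected count rests on them cannot be told. With these left out, 5 of 9 affected males remained and 221 corrected regions had an unadjusted p under 0.05 (limma). Probe patterns shared between arrays may account for most of the difference between the sexes, since their removal left 94 of 1114 regions where 805 of 1081 had been. The remaining 94 cannot be assigned: sex, reference horse and possible array batches go together, and a true difference between males and females in RAO stays open and untested.

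Of 43 sets of 4 or 8 horses tested for a horse far from its group, 2 had one, and chance gives about 1 in 20. Among the 4 summer RAO affected horses, the one from the slide of low signal had 0 corrected gains against 35 or more in the others. In the corrected region of chromosome 6 from 34420528 to 34428651, 1 summer RAO affected horse was at -0.52, apart from the other 3.

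Other splits of the same arrays were drawn 100 times for each comparison of at least 3 against 3, the real one included. For the corrected comparison of affected horses with the panel, the real split gave 2 regions and the highest other split 1. Only the real split of the 100 was as large, for the stated directions. So few regions and splits do not exclude chance. With the 6 arrays of unsettled direction turned, 0 regions passed. The single probes gave 210 over the 408170 positions with a value on all arrays or missing on the low-signal array only, against 2 in the highest other split, with 1 of 100 as large, again for the stated directions; with the 6 arrays turned 13 of all tested positions passed. For males against females the real 251 stood against 1 after correction (1 of 100) and 660 against 793 before it (2 of 100). Before correction another split of the same arrays thus gave more regions than the real one. These splits take no account of array batches, which are unknown for the panel. Affected horses and panel also differ in their breeds.

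For RAO against summer RAO after correction the real 37 stood against 31 in splits that take no account of slides, with 1 of 100 as large. Of the 100 splits that keep slides whole 3 were as large, the real one included, and the highest, RAO affected 9 to 12 on 2 slides against the rest, gave 62. Few splits were as large by either share, but slides or the breeds on them can give such counts: with slide as a random block 2 regions were left, so the 37 cannot be assigned to the disease labels.

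Where the real count is 0, all 100 splits reach it by necessity, so they say nothing about chance. This holds with centred values for affected horses against panel, Swiss Warmbloods and RAO against summer RAO (highest other values 759, 761 and 770), for carriers (3) and for corrected Swiss Warmbloods (21). Splits that call that many regions where the real one calls 0 point to a structure among the arrays that the labels do not describe.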

How the results depend on the processing

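Removal of the 2 shared patterns, the breed block, the fixed slide block, the slide block on corrected values, the arrays of unsettled direction turned or left out, the sexes apart, the left-out arrays of the slide with low signal and the left-out RAO affected 3 and 4 were chosen after seeing the data, and the other alternatives before. Of 168 alternative values of the main results, 92 kept their direction and side of the threshold, or a count within 1.5 times. Of 458 alternative values of named regions 364 did so, 46 newly passed, 46 no longer passed and 2 changed sign: chromosome 7 from 61440247, corrected and at -0.20 in affected against panel, was at 0.024 in males alone with the 6 arrays of unsettled direction turned, and chromosome 8 from 19930104, at 0.25 with scanner values in summer RAO affected against control, was at -0.024 with the series table. Where a cause is not named below, the cause was not tested.

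Calls per horse, affected minus panel (104.1), turned to -10.3 after correction, to -5.77 with the 3 doubtful affected arrays also left out and to -11.5 corrected with the 6 unsettled arrays left out. Gains (-32.2) fell short of the threshold at an absolute log2 of 0.5 (-12.8), at a score of 8 (-8.49) and with the genomic wave removed (-8.06), and changed sign to 0.59 after correction, 3.76 without the doubtful arrays, 79.7 with the 6 unsettled arrays turned (117.8 in RAO affected horses only) and, corrected, 0.458 with these turned and 0.348 with these left out. Losses (136.4) passed with RAO affected horses only (213.6, permutation p = 0.0453; 63.1, p = 0.560, with the unsettled arrays turned). Losses changed sign to -10.9 after correction, -9.53 without the doubtful arrays and, corrected, -10.8 and -11.9 with the unsettled arrays turned and left out. The 1081 regions became 1743 at an absolute log2 of 0.5, 405 at a score of 8, 5046 when merged only at the larger overlap and 1891 with the wave removed.

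Affected against panel went from 0 regions to 2 after correction (0 with the arrays of unsettled direction turned and 1 with them left out), 10 with the doubtful arrays also left out, 652 in males and 673 in females with centred values, and 38 and 18 with corrected values. With the unsettled arrays turned these 4 counts were 0, 674, 0 and 26, and with these left out 630, 767, 1 and 22. Carriers stayed at 0 under every alternative run. Probes went from 209 to 129 with no covariate, 331 with each array divided by its robust standard deviation, 13 with the unsettled arrays turned, 1195 after correction and, corrected, 2 with these turned and 461 with these left out. Swiss Warmbloods went from 0 to 264 with the later extraction protocol only, where 4 males stand against 1 panel male that is assumed to vary like the others, and stayed at 0 with each of the 3 panel horses left out.

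RAO against summer RAO went from 0 to 421 with normexp, 3 with the series table, 616 with the later protocol only, 31 without dim probes, 37 after correction, 2 corrected with slide as a random block, 496 with the arrays of unsettled direction left out, 0 with them turned and, corrected, 26 with them left out and 4 with them turned, 2 without the slide of low signal and 584 without RAO affected 3 and 4; leaving out each summer RAO horse gave 0 to 2. Its count thus depends on these choices. Summer RAO affected against control went from 0 to 10 without the slide of low signal, which leaves 1 control that is assumed to vary like the other group, and stayed at 0 with each horse left out and with slide as a fixed block.

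Males against females went from 660 to 11 with all horses, 1302 with the wave removed, 127 with breed as a fixed block, 251 after correction and 212 with both of these, and on X from 77 to 1, 126 with the wave removed, 32 with the breed block and 117 with the unsettled arrays left out. Corrected, 363 passed with the unsettled arrays turned and 348 with these left out. Przewalski's Horse went from 1 to 3 with the wave removed, 3 and 4 with the unsettled arrays turned and left out, 40 after correction and, corrected, 46 and 49 with these turned and left out, and leaving out either horse gave 0 to 3 with centred and 9 to 47 with corrected values; the lone horse is then assumed to vary like the others.

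The alternatives foreseen for gene lists and for 2 loci were not run, since no probe was paired with a gene. No paired analysis was possible because the replicate numbers were given in sample order and pair no horses; the breed and slide blocks above group horses by breed and by slide instead. Signal over background limits what the 2 arrays of the low-signal slide can show.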

Other observations

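The comparison of shared patterns with the chromosome 16 gain and with the numbers of calls was chosen after these had been seen. The tests of probe classes, breakpoint, other chromosomes, array noise and signs were fixed before their values were computed.

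The male Przewalski's Horse carried a long run of gains on chromosome 16 that no other array showed. From 53289211 to 87364803, the last position of the chromosome, its mean log2 ratio over 5865 positions was 0.36 with centred and 0.41 with corrected values, 90.3% of positions lay above 0, and 53 other arrays (those of the low-signal slide left out) lay between -0.06 and 0.02, the female Przewalski's Horse at -0.01 among them. From 13 to 43 Mb the same array lay at -0.14, below the range of these 53 (-0.03 to 0.03), and from 43 to 53 Mb at 0.10 (highest of the 53 at 0.02), with 0.42 from 49 to 50 Mb, so it was raised before the stated start and the profile is not a single step. On chromosome 6 from 745265 to 4747722 the horse was at 0.24 with centred and 0.41 with corrected values, with a highest corrected value of 0.07 in these 53, but the 200 positions before the start were already at 0.25, so that the step there was 0.12.

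The chromosome 16 run may be a biological change in this horse, which is a hypothesis found and tested on the same array. Shared probe patterns are argued against by the corrected mean of 0.41, a single class of probes by a mean of 0.31 in the class with the lower mean, and waves of this size elsewhere on the array by 0.12, the largest mean of a window of as many positions on 27 other autosomes. A gradual wave along the chromosome cannot be told apart: values over 200 positions rose by 0.27 at the first breakpoint, but that breakpoint was placed by the search on the same values, which favours a step there, and values were raised before it. With 1 array of this horse, no repeat of the measurement is available here.

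The number of calls differed widely between arrays. The most calls over the median number was 5.32 with centred and 2.47 with corrected values, and the corrected difference between affected horses and panel had a permutation p of 0.257, with fewer calls in affected horses. Over 54 arrays outside the slide of low signal, calls did not rise with the robust standard deviation of the array (Pearson r = 0.013, permutation p = 0.927, Spearman rho = 0.062, permutation p = 0.655, r = 0.041 without the 2 extreme arrays; adjusted p = 0.927 and 0.655 over 2 relations). Corrected calls fell with it (r = -0.303, permutation p = 0.0271, rho = -0.309, permutation p = 0.0234, r = -0.315 without the 2 extreme arrays; adjusted p = 0.0542 and 0.0467).

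An exchange of dyes on some arrays was tested as a reason for correlations below -0.3. Over regions where 90% of panel arrays of a reference share a sign and the absolute mean exceeds 0.2, the lowest share of regions with the majority sign was 0, in the female Sorraia horse, but over 1 region. Other female arrays had 0 such regions, and the lowest male share was 0.2 over 20 regions in RAO affected 10, so an exchange of dyes could not be decided. Looser limits, 85% with 0.15 and with 0.1, were tried after these shares had been seen. They gave a share of 0 over 10 and over 24 regions for the Sorraia, and 0.247 over 81 and 0.223 over 130 regions for the Mongolian Native Horse numbered 24 in the panel. Affected horses came next among the males: RAO affected 10 had 0.271 and 0.273, RAO affected 3 0.282 and 0.333, RAO affected 4 0.341 and 0.38 and RAO affected 7 0.341 and 0.307, over 85 and 150 regions. At the first limits RAO affected 3 had 0.25 over 20 regions, RAO affected 7 0.3, RAO affected 4 0.4 and that Mongolian Native Horse 0.294 over 17. Among females after the Sorraia, the lowest share at 85% with 0.15 was 0.429 over 7 regions, in the Percheron numbered 27 in the panel. With 0.1 it was 0.5 over 14 regions, in RAO affected 1. Arrays of the low-signal slide were not checked. RAO affected 7 correlated at 0.93 with each of RAO affected 5, 6 and 8 over centred autosomal values. With RAO affected 5 it correlated at 0.54 after correction. These values argue against turning it without those arrays, as was done here. The check of signs did not settle the direction of the 6 arrays, which bears on the comparisons of affected horses, and that of the other females was hardly tested. The stated direction was kept.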
